A study of Mus musculus with 4 samples.

How the data were processed

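RNA was measured by 3-prime single-cell sequencing of cells sorted from femur bone marrow, with 4 libraries, 1 for each of Ctrl, Sham_D40, Graft_D19 and Graft_D40. Per the labels' protocols, marrow was digested, depleted with beads and sorted as Cd45 and Ter119 negative, Cd31 negative, Cd51 positive, Cd200 positive stroma and Cd31 positive, Sca1 positive endothelium, and human CD20 positive lymphoma cells were also sorted. The deposited values are raw UMI counts per gene and barcode. Per the file headers, the count matrices were written by Cell Ranger 5.0.0, whereas the submitters' processing notes give Cell Ranger 3.1.0 and the mouse build mm10. Gene positions were taken from GENCODE vM21 on the same build, in which 32235 of 32285 genes (99.8%) were found. Sham_D40 and Graft_D40 each hold 2 antibody features whose meaning is not given in the sources used here. They were left out of all totals. Between any 2 libraries 11 to 15 barcodes were shared.

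Cells were kept at 500 or more genes, 1000 or more UMIs and at most 10% mitochondrial UMIs, which left 4151, 4570, 4902 and 4920 cells in Ctrl, Sham_D40, Graft_D19 and Graft_D40. Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 6%, and 77, 43, 89 and 53 cells were removed. Counts were scaled to 10000 per cell, log transformed, reduced to 2000 variable genes and 30 principal components, and clustered with 15 neighbours by the Leiden method at resolution 1.0 and seed 1 (igraph 0.11.9), without alignment of libraries. A cluster was named when 3 or more markers of a type were at least 2-fold above the other cells and present in 25% or more of its cells. It entered comparisons under that name when its 10 leading genes did not hold more markers of another type. Cluster 4 failed this for LepR-like stroma and entered the pooled mesenchymal stroma alone. Clusters 20, 22 and 24 failed it and entered no pooled class. The unnamed clusters 9, 16 and 23, pericyte-like cluster 15 and haematopoietic cluster 21 were left out of comparisons.

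UMIs were summed over the cells of a class in each library and divided by the class total to give CPM, the UMI counts of a gene scaled to a common class total, with exact Poisson intervals. Log2 ratios used a pseudocount of 1 CPM, and ratios carry exact conditional binomial intervals at 95%. Shares of cells carry Clopper-Pearson intervals. Gene lists, among them the extracellular matrix list joined from 4 sublists, the activated-fibroblast list and the niche factor list, were written before the data were examined, as were the comparisons, the filters and the alternatives below unless stated. A list member was measured at a mean of 5 CPM or more, and called higher or lower at 1.5-fold or more with an interval off 1. List medians carry intervals from 1000 Poisson resamples. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Poisson counts were simulated from these totals, under the same counting model as the intervals. The intervals covered the true ratio for 95.1% of 10760 genes. Of genes set to a 1.5-fold change 54.0% were called, of those set to 2-fold all, and of 10560 unchanged genes 0. This checks the calculation and says nothing of spread between cells or libraries.

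Graft_D40 was compared with Sham_D40 and Graft_D19 with Ctrl. Sham_D40 over Ctrl served as the scale of differences between ungrafted libraries, and the other ungrafted library was tried as comparator. Antibody features are held by Sham_D40 and Graft_D40 but not by Ctrl and Graft_D19. The scale and both swapped comparators cross that split, whereas the 2 main comparisons stay within it. Whether the libraries were prepared apart along it is not known, so these values may hold more than ordinary spread between libraries. With 1 library per group no p-value was computed and animal, day and library cannot be separated from the group. Ctrl is the shallowest library, with 9658928 UMIs in mesenchymal stroma against 35349674 in Sham_D40, 39168298 in Graft_D19 and 45775200 in Graft_D40; in endothelium the totals were 6061731, 9279915, 11642496 and 9104698. A gene with 3 counts in Ctrl mesenchymal stroma is at 0.311 CPM. Genes named in the text are those at 50 CPM or more in the grafted or both ungrafted libraries that differed the same way from Sham_D40 and Ctrl, ranked by the smaller log2 ratio. The first 10 in each direction at day 40 and the first 5 at day 19 were taken, without mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, Y-linked, Xist and Tsix, unnamed and haematopoietic genes. Of these, 1 is not reported here. Fixed matrix, niche and endothelial genes were added, with the 2 to 4 most different members of each list at 20 CPM or more. Genes of the pooled LepR-marker clusters, of the LepR-like and sinusoidal-like subsets and of osteolineage-like cells were chosen after their values were seen.

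Alternatives tried were 2 other scalings, a pseudocount of 5 CPM, no minimum or 50 CPM for list members, stricter and looser cell filters, doublets kept, resolutions 0.5 and 2.0, classes from each cell's highest marker list, equal weight per cell, and cells thinned to 2000 UMIs. Clustering without the matrix and activated-fibroblast genes, mesenchymal stroma without chondrocyte-like clusters and the pool of all clusters with LepR markers were chosen after the data were seen. Human reads were not analysed here.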

Results

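Single-cell RNA was measured in sorted bone marrow stroma and endothelium of femurs from immunodeficient Rag2-deficient, common gamma chain-deficient C57BL/6 mice. The grafted femurs had received DOHH2, an established human follicular lymphoma B-cell line. There were 4 libraries in 4 groups: an ungrafted control (Ctrl), a sham injection at day 40 (Sham_D40), and grafts at day 19 (Graft_D19) and day 40 (Graft_D40). Each group had 1 library and no replicates, so no difference between groups was tested, and every interval given here covers counting error only. Ctrl held 5537 barcodes and 18533482 gene UMIs, Sham_D40 5750 and 51744386, Graft_D19 7668 and 63214301, and Graft_D40 6674 and 72204599. Median UMIs per barcode were 2506 in Ctrl, 7376.5 in Sham_D40, 5187 in Graft_D19 and 7021.5 in Graft_D40. After filtering and removal of called doublets, 4074, 4527, 4813 and 4867 cells remained in that order, in 25 clusters.

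The mesenchymal stroma comprised 2341 cells in Ctrl, 2990 in Sham_D40, 3108 in Graft_D19 and 2847 in Graft_D40. It held LepR-like cells, the perivascular stroma that expresses the leptin receptor and supplies blood stem cells with growth factors, in clusters 1, 2, 5, 7 and 13. Osteolineage-like cells filled clusters 6 and 14, chondrocyte-like cells clusters 0, 18 and 19, and fibroblast-like cells cluster 17. Cluster 4 carried 7 of the 12 LepR stromal markers at 2-fold or more, but its leading genes held 0 of them and 1 fibroblast marker, so it is given by number. Clusters 20 and 22 also failed their marker check and count only in the total of mesenchymal cells on which shares are based. Endothelium was mostly sinusoidal-like (clusters 3, 8 and 12), with arterial-like cluster 11 and a further endothelial cluster, 10. Cluster 24 carried 12 endothelial markers at 2-fold or more. Its leading genes held 0 endothelial markers and 1 gene of the megakaryocyte list, Vwf, so it failed its marker check. It made up 0.927% of endothelial cells in Ctrl, 6.03% in Sham_D40, 3.40% in Graft_D19 and 13.97% in Graft_D40. It counts only in the endothelial total, and the endothelial gene results leave it out. The cells had been sorted as Cd51-positive Cd200-positive stroma and Cd31-positive Sca1-positive endothelium, so shares are given within each compartment and describe the sorted cells.

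The cells sorted and pooled as mesenchymal stroma held, in the grafts, a cluster that the ungrafted libraries almost lacked. Cluster 4 was 0.966% of mesenchymal cells in Ctrl, 1.06% in Sham_D40, 19.7% in Graft_D19 and 40.8% in Graft_D40. Among clusters 1, 2, 4, 5, 7 and 13, all of which carried LepR stromal markers, cluster 4 made up 1.28% (0.8103 to 1.91) of cells in Ctrl and 1.59% (1.095 to 2.22) in Sham_D40. The share was 34.03% (31.9 to 36.2) in Graft_D19 and 79.1% (76.96 to 81.1) in Graft_D40 (Clopper-Pearson intervals). Because genes of the extracellular matrix (ECM, the collagens, glycoproteins and enzymes of the space between cells) led cluster 4, the cells were also clustered without the matrix and activated-fibroblast genes. That clustering again gave 1 such cluster, which held 1716 of the 1913 cells of cluster 4 and made up 2.04%, 3.26%, 39.7% and 82.7% of LepR-marker cells in Ctrl, Sham_D40, Graft_D19 and Graft_D40. Within Graft_D40 its cells exceeded the other LepR-marker cells in the matrix list (median log2 0.48, 34 of 95 genes at least 1.5-fold higher and 4 lower), in collagens (0.66, 14 of 21 higher) and in activated-fibroblast genes (0.46, 8 of 19 higher). In sinusoidal-like endothelium cluster 12 made up 7.83% of cells in Ctrl, 16.3% in Sham_D40, 49.4% in Graft_D19 and 83.1% in Graft_D40. The 2 ungrafted libraries also parted there, with cluster 8 at 61.8% in Ctrl and 13.7% in Sham_D40, and cluster 3 at 30.4% and 70.1%. They parted among the LepR-marker clusters too, with cluster 1 at 63.9% in Ctrl and 0.914% in Sham_D40, and cluster 2 at 12.4% and 55.8%. Splits between the libraries, which were not aligned, were thus not particular to the grafts.

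**Figure D1:**
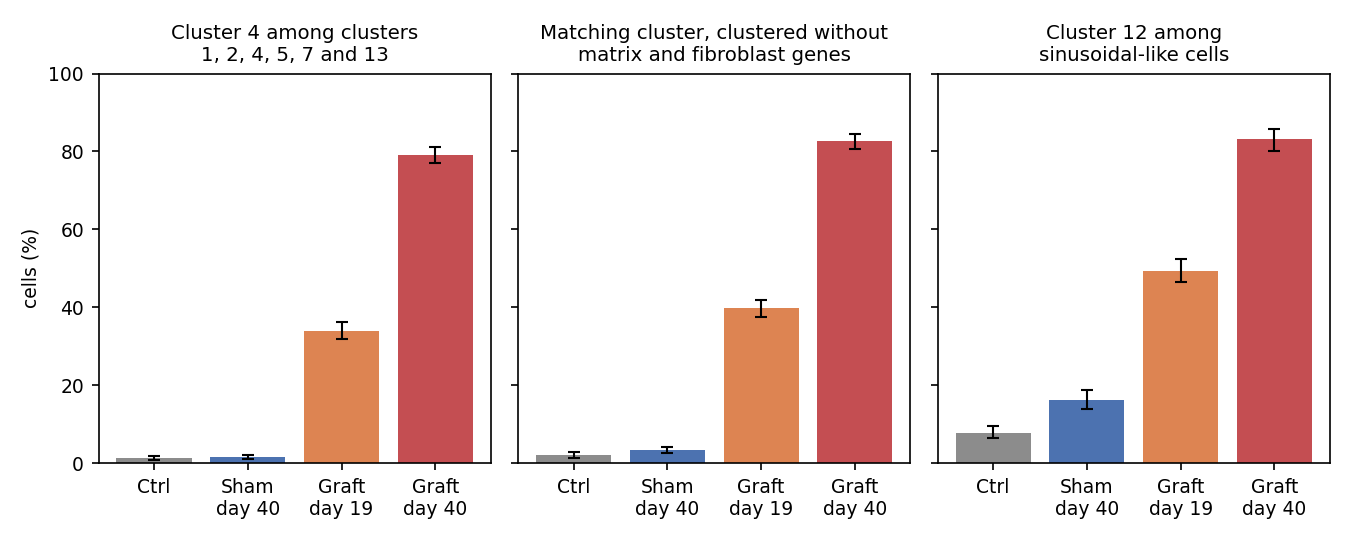
Percent of cells per library (bars, with 95% Clopper-Pearson intervals) in cluster 4 among clusters with LepR stromal markers, in its matching cluster when matrix and fibroblast genes were left out, and in cluster 12 among sinusoidal-like cells. Each share was highest in Graft_D40, at 79.1%, 82.7% and 83.1%.

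The first comparison, Graft_D40 over Sham_D40, asks how an established lymphoma graft alters the stroma. In clusters 1, 2, 4, 5, 7 and 13 as 1 pool, a group formed after the data were seen, genes for interstitial matrix and its remodelling stood far above sham. 52 of 94 measured matrix genes were at least 1.5-fold higher and 6 lower (median log2 0.67, against Ctrl 1.15), and so were 15 of 21 collagens (median 1.35). In cluster 4 alone, with 33 cells in Sham_D40, the medians were 0.72 for fibrillar and 0.38 for other collagens. They were 0.29 for matrix glycoproteins and proteoglycans and 0.34 for matrix enzymes. Part of the pooled difference therefore goes with the larger share of cluster 4. Col1a1 (collagen I; ENSMUSG00000001506, chromosome 11, 94936224 to 94953042, mm10) was at 2469 CPM against 212 CPM, 11.7-fold (interval 11.3 to 12.04) higher. Col3a1 was at 1086 against 157 CPM, the microfibrillar collagen gene Col6a3 at 314 against 21.9 CPM, and fibronectin, Fn1, at 296 against 44.9 CPM. The matricellular gene Postn (periostin) was at 115 against 2.32 CPM and Fbln2 (fibulin 2) at 82.2 against 1.003 CPM. The gelatinase gene Mmp2 stood at 172 against 12.6 CPM and the protease inhibitor gene Timp1 at 398 against 78.1 CPM. The 5 LepR-like clusters without cluster 4, of which Graft_D40 held 324 cells, had a matrix median of 0.09, with 20 of 89 genes higher and 4 lower, and a median of 0.33 at resolution 2.0 and 0.42 by marker list. The higher genes include Timp3 (209 against 41.4 CPM), Mmp11 (138 against 38.4 CPM) and Igfbp3 (713 against 238 CPM). From Sham_D40 to Graft_D40, Fbln2 rose by 183 CPM in endothelium and 81.2 CPM in the pool, and Igfbp3 by 524 and 244 CPM. For either gene, RNA from other cells is therefore not argued against.

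Contractile and activated-fibroblast genes accompanied the matrix genes in the LepR-marker clusters. Of the 25 activated-fibroblast genes, 4 are also in the matrix list (Cthrc1, Fap, Postn and Tnc) and 2 are pericyte markers (Acta2 and Tagln). Acta2 (smooth muscle actin; ENSMUSG00000035783, chromosome 19, 34241090 to 34255590) was at 282 CPM in Graft_D40 against 1.74 CPM in Sham_D40, and its cytoskeletal partner Tagln at 229 against 3.38 CPM. S100a4, a motility-linked calcium-binding gene, was at 244 against 6.49 CPM. The activated-fibroblast list had a median log2 of 1.37 there, with 11 of 19 genes higher and 2 lower. The TGF-beta response list had a median of 0.70, 14 of 24 higher, with the feedback gene Pmepa1 at 809 against 228 CPM and the ligand gene Tgfb3 at 67.02 against 23.3 CPM. Cluster 4 alone held 33 cells in Sham_D40 and 23 in Ctrl. Its activated-fibroblast median was 0.57 over Sham_D40 (8 of 19 higher, 2 lower). Over Ctrl it was 0.20, with 2 higher and 1 lower, and neither Acta2 nor Tagln was among the higher. Its TGF-beta median was 0.57 over Sham_D40 (9 of 24 higher, 2 lower) and 0.22 over Ctrl (3 higher, 2 lower). The 10 mesenchymal cells with most Acta2 UMIs held 41.4% of the 4634 Acta2 UMIs of Graft_D40 mesenchymal stroma, against 44.9% in Ctrl, 58.3% in Sham_D40 and 60.4% in Graft_D19. Without those 10 cells the level was 59.4 CPM in Graft_D40 and 1.27 CPM in Sham_D40. An Acta2 UMI was found in 335 of 2847 mesenchymal cells of Graft_D40 (11.8%), and 1 cell held 541. Only 37 cells in Ctrl, 55 in Sham_D40 and 76 in Graft_D19 had any, so 10 cells are a larger part of them. The shares of the top 10 cells therefore do not compare concentration between libraries.

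Factors that support haematopoiesis were lower in the same cells. Kitl (stem cell factor; ENSMUSG00000019966, chromosome 10, 100015630 to 100100416) was at 899 CPM in Graft_D40 against 2801 in Sham_D40, 3.11-fold (interval 3.06 to 3.17) lower. The retention chemokine gene Cxcl12 (ENSMUSG00000061353, chromosome 6, 117168535 to 117181367) was at 17316 against 35157 CPM, and the adhesion gene Vcam1 at 1060.1 against 2377 CPM. Bmp4 (a bone morphogenetic protein) was at 126 against 450.4 CPM, the vessel factor Angpt1 at 140.1 against 385 CPM and the lymphoid cytokine gene Il15 at 17.2 against 49.1 CPM. The niche factor list, which shares 6 genes with the LepR stromal markers that named these clusters, had a median log2 of -0.72, with 11 of 20 genes lower and 2 higher. Lepr itself was at 1718 against 2173 CPM. Of the adipogenic list, which also shares 6 genes with those markers, 6 of 18 were lower and 2 higher (median -0.44). The shared genes Lpl (a lipase) and Adipoq (adiponectin) were at 1267 against 5337 CPM and 911 against 3169 CPM. In cluster 4 alone, with 33 cells in Sham_D40, the niche median was -0.62 over Sham_D40 (10 of 20 lower, 0 higher). Over Ctrl, with 23 cells of that cluster, it was -0.20, with 5 lower and 0 higher. Kitl was among those 5, but neither Cxcl12 nor Vcam1 was.

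In the LepR-marker clusters of Graft_D40, 8 of 16 cytokine and chemokine genes were higher than in sham and 4 lower (median log2 0.43). The interferon-induced chemokine genes Cxcl10 and Cxcl9 were at 88.2 against 1.05 CPM and 88.1 against 12.4 CPM, and the interferon list had a median log2 of 0.40 (14 of 34 higher). In cluster 4 alone the interferon median was 0.03 over Sham_D40, with 3 higher and 3 lower, and -0.74 over Ctrl. Its cytokine and chemokine median was 1.26 over Sham_D40 (6 of 19 higher, 2 lower) and -0.41 over Ctrl (1 higher, 6 lower). Cxcl9 and Cxcl10 were higher there than in Sham_D40 but lower than in Ctrl. Cxcl13, which attracts B cells into follicles, was at 228 against 11.8 CPM in the pool, and at 33.5 CPM in Ctrl. In cluster 4 alone Cxcl13 was higher than in Sham_D40 but lower than in Ctrl, which held 23 cells of that cluster. In the lipid and cholesterol list 15 of 21 genes were higher and 2 lower (median 0.98), while in cluster 4 alone, with 33 cells in Sham_D40, 4 were higher and 3 lower. Those higher in the pool include the sterol synthesis genes Fdps (41.95 against 9.76 CPM) and Cyp51 (36.5 against 9.66 CPM). Of the hypoxia and glycolysis list 11 of 23 were higher (median 0.49), and 7 in cluster 4 alone. The glycolytic genes Eno1 (113 against 36.99 CPM), Pkm (185 against 62.4 CPM) and Pgk1 (96.1 against 34.6 CPM) were among them. In the LepR-like clusters without cluster 4, 20 of 31 immediate early genes were higher, among them Jun (1480.4 against 449 CPM), Ier2 (306 against 73.3 CPM) and Klf4 (176 against 50.9 CPM), which tissue digestion also induces. In arterial-like endothelium this list went the other way over Sham_D40, with a median of -0.40, 2 of 31 higher and 8 lower. Cluster 13, led by the immediate early gene Egr1, held 83 of the 324 LepR-like cells without cluster 4 in Graft_D40. In Sham_D40 it held 277 of 2046. How far the immediate early difference goes with that share was not tested.

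Over the whole mesenchymal stroma, niche genes were lower at day 40, and the matrix difference from Sham_D40 was small. The niche factor list had a median log2 of -1.34, with 16 of 20 genes lower and 0 higher, and a median of -0.86 without chondrocyte-like clusters. Kitl was at 319 against 1598 CPM, 5.01-fold lower, Cxcl12 at 5937 against 19861, Vcam1 at 378 against 1345, Lepr at 598 against 1223 and the lymphoid cytokine gene Il7 at 43.4 against 103 CPM. Matrix genes split, 25 higher and 18 lower of 104 (median 0.16, against Ctrl 0.93, and 0.42 over Sham_D40 without chondrocyte-like clusters), while collagens leaned higher (10 of 25, median 0.44). Col1a1 was at 16087 against 7902 CPM and Col1a2 at 12507 against 7264. Col3a1 (1064 against 904 CPM), Fn1 (3001 against 2626), Postn (86.2 against 66.3), Tgfb1 (101 against 79.7), the fibroblast protease gene Fap (291 against 265) and Pdpn, podoplanin (10.7 against 9.31), each differed by less than 1.5-fold. The activated-fibroblast median was 0.06, with 5 of 21 genes higher and 3 lower. The adipogenic list was lower (12 of 18 genes, median -0.92), and the lipid list higher (11 of 21, median 0.58).

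Genes ranked by their difference from both ungrafted libraries put Acta2 and Tagln first in mesenchymal stroma of Graft_D40. Acta2 was at 101 CPM against 3.06 in Sham_D40 and 5.07 in Ctrl, 33.1-fold (interval 27.4 to 40.5) higher than in Sham_D40, and Tagln at 83.6 against 3.71 and 6.94 CPM. The other 8 high-ranked genes were C1qtnf3, Il17b, Pcp4, Pcolce2, Csrp2, Panx3, Ihh (Indian hedgehog) and Epyc, with log2 ratios over sham from 1.80 to 2.60, and several of them are products of cartilage or growth plate. Chondrocyte markers as a set had a median log2 of 1.24 in mesenchymal stroma, and of 1.38 in endothelium, which should lack them, and erythroid markers of -3.66 and -2.18. Chondrocyte-like cells made up 26.8% of mesenchymal cells in Graft_D40, 20.9% in Graft_D19, 13.2% in Sham_D40 and 9.92% in Ctrl. The lowest-ranked genes were Timp4, Col6a5, Serpina3n, Adipoq, Slc26a7, C2, Bmp4, Adcyap1r1, Chl1 and Kitl, with log2 ratios from -3.10 to -2.32, and Adipoq and Kitl are markers of LepR-like stroma.

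Osteolineage-like cells also had lower niche genes, and fibroblast-like cells had higher interferon and antigen presentation genes. In osteolineage-like cells, 17 of 20 niche genes were lower (median log2 -1.34), with Cxcl12 at 1235 against 5647 CPM and Kitl at 128 against 548 CPM. Their collagens leaned higher (12 of 23, median 0.61). The antiviral gene Rsad2 was at 87.9 against 0.779 CPM there. In fibroblast-like cells, 24 of 31 interferon genes (median 1.18) and 10 of 12 antigen presentation genes (median 1.14) were higher, from 144 cells in Graft_D40 and 148 in Sham_D40. Their niche median was -0.22, with 5 of 20 genes lower and 1 higher, and their matrix median 0.09, with 17 of 103 higher and 12 lower. Osteolineage-like cells made up 11.4%, 11.2%, 15.3% and 11.7% of mesenchymal cells in Ctrl, Sham_D40, Graft_D19 and Graft_D40. Within them cluster 14, led by Col1a1 and Bglap2, held 73 of 351 cells in Sham_D40 and 145 of 351 in Graft_D40. Its cells had a median of 25603.5 UMIs against 7695.5 in cluster 6, so summed CPM leans to cluster 14. Whether the niche and collagen differences of osteolineage-like cells lie within either cluster was not tested.

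**Figure D2:**
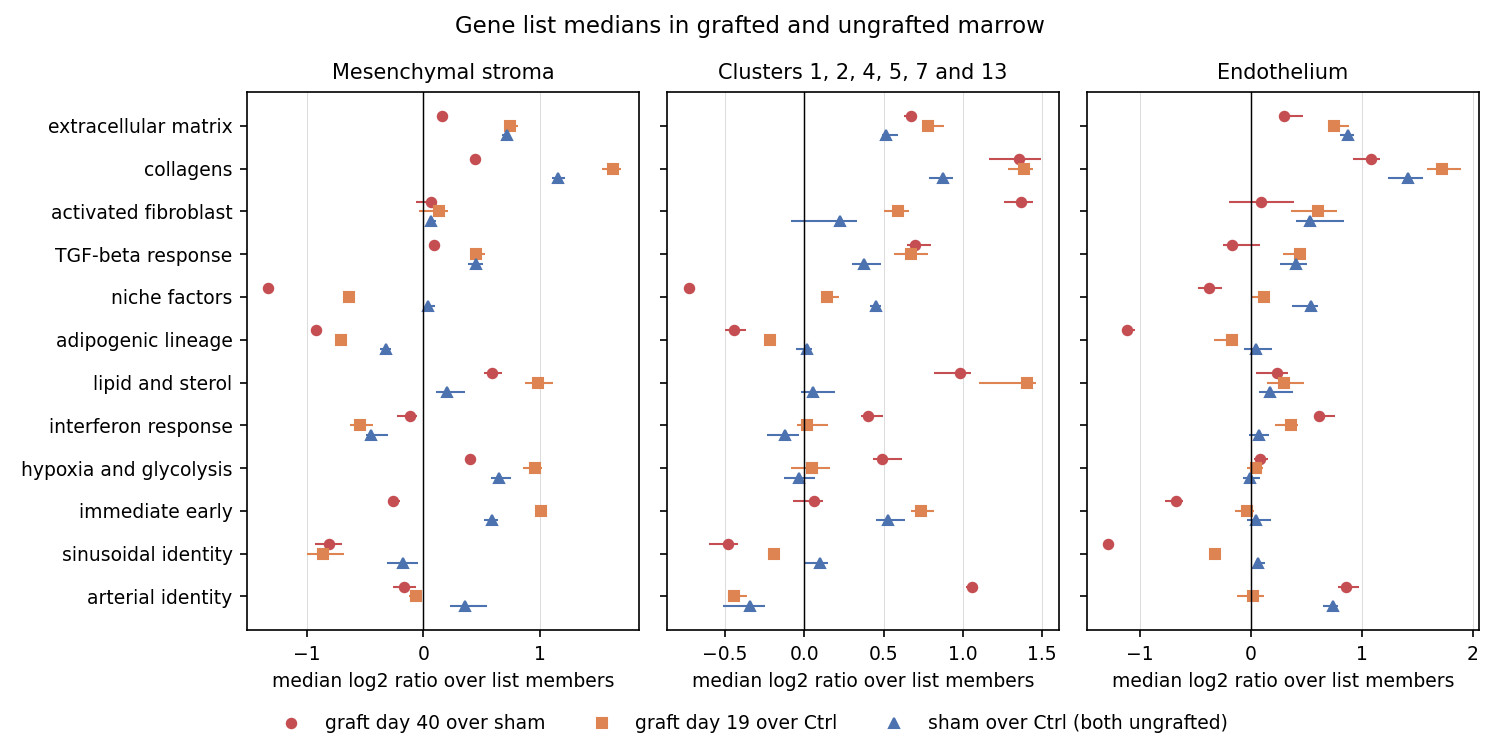
Median log2 ratio (horizontal axis) of 12 gene lists in mesenchymal stroma, in the clusters with LepR stromal markers and in endothelium, for Graft_D40 over Sham_D40, Graft_D19 over Ctrl and, for scale, Sham_D40 over Ctrl; lines are 95% resampled counting intervals. At day 40 niche factors lay at -1.34 in mesenchymal stroma, collagens at 1.35 in LepR-marker clusters and sinusoidal identity at -1.29 in endothelium.

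The second comparison, Graft_D19 over Ctrl, asks which differences are present early. Mesenchymal stroma of Graft_D19 showed more matrix and cartilage RNA than Ctrl, a matrix difference that the sham library shared, and less niche RNA when chondrocyte-like cells are included. 59 of 104 matrix genes were higher in Graft_D19 (median log2 0.75) and 63 in Sham_D40 over Ctrl (median 0.72), and against Sham_D40 the Graft_D19 median was -0.03. Col1a1 was at 13677 CPM against 4945 in Ctrl and 7902 in Sham_D40, Col1a2 at 10989.7 against 4504 and 7264, and Fn1 at 2797 against 421 and 2626. Col3a1 was higher than in Ctrl (566 against 169 CPM) and lower than in Sham_D40 (904 CPM). Niche genes had medians of -0.64 over Ctrl and -0.69 over Sham_D40, where Sham_D40 over Ctrl gave 0.04. Without chondrocyte-like clusters the median over Ctrl was -0.048, and with equal weight per cell it was -0.15, so most of this difference goes with the UMIs of chondrocyte-like cells. Kitl was at 763 CPM against 1632 in Ctrl, Cxcl12 at 11511 against 24638, Vcam1 at 712 against 1316, Il7 at 64.1 against 85.4 and Lepr at 922 against 1239 CPM. Acta2 was at 5.41 against 5.07 CPM, Postn at 66.6 against 55.7, Fap at 261 against 332, Pdpn at 6.71 against 5.38 and Tgfb1 at 94.5 against 55.5 CPM. The activated-fibroblast median was 0.13.

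Ranked against both ungrafted libraries, the top genes of Graft_D19 mesenchymal stroma were the cartilage products C1qtnf3, Col9a1, Il17b, Col9a3 and Ihh, and the lowest were Adcyap1r1, Efemp1, Ccdc152, Serpina3n and C2. Chondrocyte markers had a median log2 of 2.55 over Ctrl in mesenchymal stroma and 1.87 in endothelium. In the LepR-marker clusters, 14 of 21 lipid and cholesterol genes were higher and 1 lower over Ctrl, with a median of 1.40 over Ctrl and 1.03 over Sham_D40, and with Cyp51 at 45.2 against 10.8 CPM. The matrix median of these clusters was 0.78 over Ctrl and 0.18 over Sham_D40. Col1a1 was at 442 CPM in them, between sham (212) and Graft_D40 (2469). Their niche factor median was 0.14 over Ctrl and -0.24 over Sham_D40. Over all measured genes the median of Graft_D19 over Ctrl was 0.27 in the LepR-like clusters without cluster 4 and 0.09 in mesenchymal stroma. List medians over Ctrl are to be read against these values. The LepR-like clusters without cluster 4 had a matrix median of 0.70 over Ctrl and 0.055 over Sham_D40. Of the immediate early genes, 18 of 28 were higher in LepR-marker clusters (median 0.74, where Sham_D40 over Ctrl gave 0.53), with Fosb at 371 against 31.1 CPM.

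Endothelium of Graft_D40 carried more collagen and interferon RNA and less sinusoidal RNA than Sham_D40. The sinusoidal identity list had a median log2 of -1.29, with 16 of 18 genes lower, and the arterial list one of 0.86, with 13 of 20 higher; the lists hold the 12 sinusoidal and 14 arterial markers that named the clusters. The scavenger receptor gene Stab2 (ENSMUSG00000035459, chromosome 10, 86841198 to 87008025), typical of sinusoids, was at 347 against 1235 CPM, 3.56-fold (interval 3.42 to 3.703) lower. Vcam1 (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688) was at 102 against 743 CPM, 7.29-fold (interval 6.803 to 7.81) lower, and the venular chemokine receptor gene Ackr1 at 95.8 against 433. Ly6a (Sca1, also a sorting marker) was at 1857 against 782 CPM, the gap junction gene Gja5 at 79.3 against 20.3, Pecam1 (Cd31) at 1089.7 against 701 and the VEGF receptor gene Kdr at 1033 against 1654 CPM. Within sinusoidal-like cells, of which cluster 12 made up most at day 40, the sinusoidal median was again -1.30 and the arterial median 1.32, with Stab2 at 457 against 1473 CPM. In cluster 12 alone the sinusoidal median was -0.48 (7 of 18 lower) and the arterial median -0.23 (5 higher and 6 lower), so the arterial excess goes with the change of clusters. The sinusoidal-like share of endothelial cells was 76.9% in Ctrl, 69.3% in Sham_D40, 87.8% in Graft_D19 and 55.9% in Graft_D40. Both graft shares depended on the processing. Under a looser cell filter they were 57.2% and 17.7%, and by marker list 38.2% and 9.45%, so that Graft_D19 lay below both ungrafted libraries.

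The endothelial ranking was led by Apln and Col18a1, while the angiogenesis list over Sham_D40 had a median of 0.19, with 7 of 24 genes higher and 4 lower. Apln (apelin, a ligand made by sprouting vessels; ENSMUSG00000037010, chromosome X, 48025146 to 48034853) was at 52.3 CPM in Graft_D40 against 5.603 in Sham_D40, 9.33-fold (interval 6.997 to 12.7) higher, and at 49.5 in Graft_D19 against 2.804 in Ctrl. Col18a1, the endostatin precursor gene (ENSMUSG00000001435, chromosome 10, 77052178 to 77166548), was at 231 against 36.1 CPM, and Col4a1, collagen IV, at 1797 against 691 CPM. The basement membrane linker gene Nid2 was at 118 against 27.6 CPM, Igfbp3 at 644 against 119.9, Igfbp5 at 1489 against 289 and the mechanosensitive channel gene Piezo2 at 100.5 against 17.3 CPM. Slfn2, Olfml2a, Ednrb and Endod1 completed the 10 highest, with log2 ratios from 1.98 to 2.47. Piezo2 and Ednrb are leading genes of cluster 12, so their difference and the share of that cluster are 1 finding. Cfd (complement factor D) was lowest, at 3.405 against 124 CPM, and others among the lowest were Cxadr, Tmem273, Dclk1, Ptger2, Rarres2, Hp, Cyp4b1 and Ackr1. Cxadr, Cyp4b1, Ackr1 and Stab2 are leading genes of clusters 3 and 8, so their difference goes with the smaller share of those clusters. 13 of 19 collagens were higher (median 1.08), and of the whole matrix list 34 of 80 were higher and 13 lower (median 0.30, and 0.52 to 0.73 under other resolutions, cell filters and cell classes). The higher collagens include cartilage and bone genes such as Col2a1, Col10a1, Col11a2 and Col1a1, and chondrocyte markers had a median of 1.38 in the same cells. 19 of 35 interferon genes were higher and 0 lower (median 0.61), led by Cxcl10 (67.5 against 11.7 CPM), Rsad2 (348 against 88.04 CPM) and the regulator gene Irf7 (121 against 39.2 CPM). The interferon median was also 0.57 in sinusoidal-like and 0.59 in arterial-like cells, where it was 0.27 over Ctrl and Sham_D40 itself was lower than Ctrl (-0.29).

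**Figure D3:**
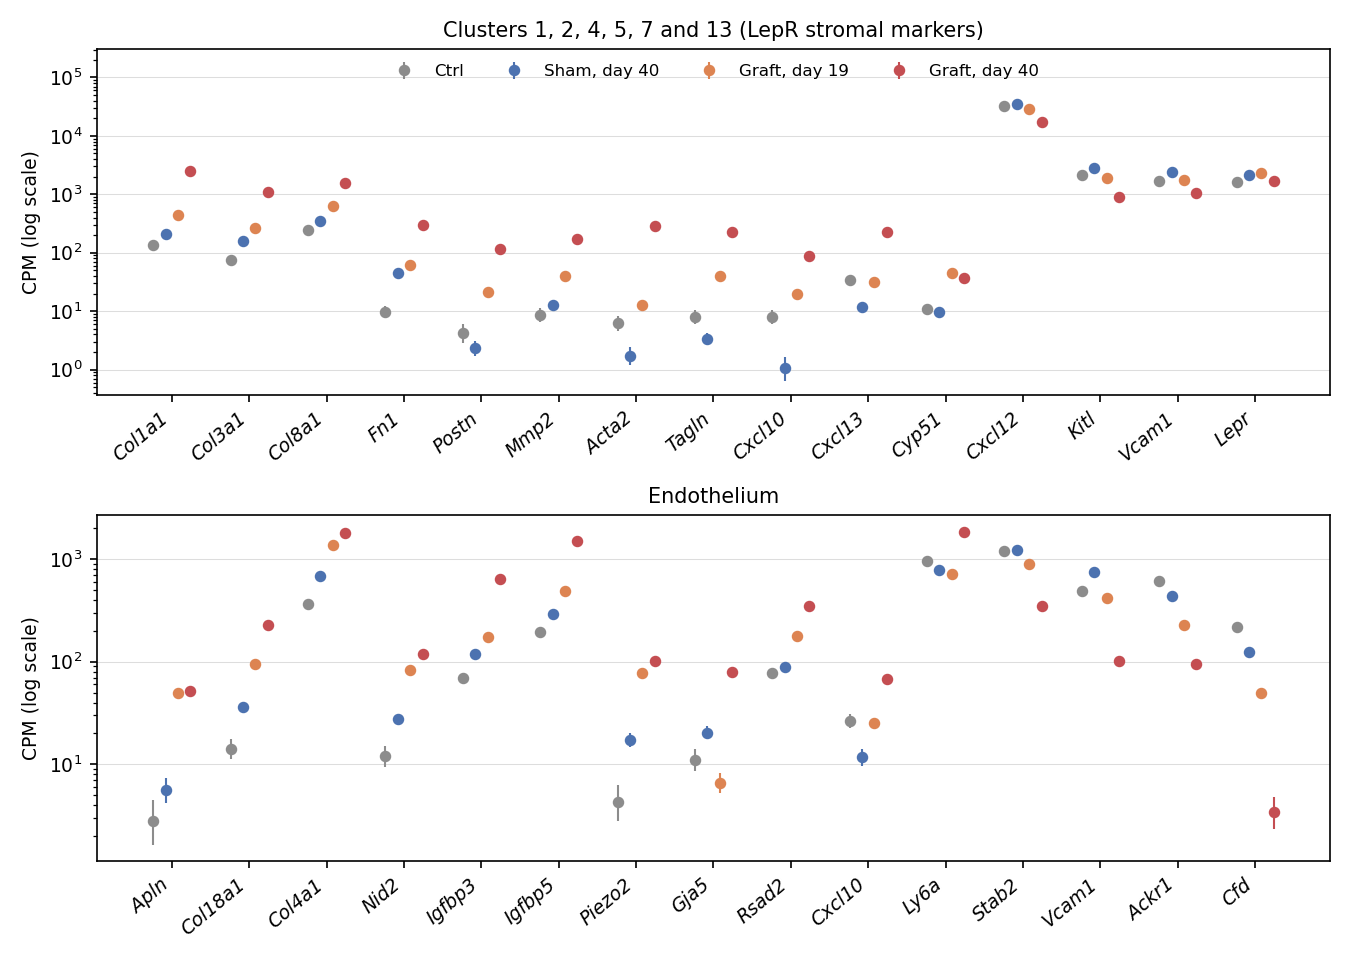
CPM (vertical log axis, with 95% Poisson intervals) of selected genes in each library, in clusters with LepR stromal markers (top) and in endothelium (bottom). Acta2 stood at 282 CPM in LepR-marker clusters of Graft_D40 against at most 12.6 CPM in the other libraries, and endothelial Apln near 49.5 and 52.3 CPM in the grafts against 2.804 and 5.603 CPM without.

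Endothelium of Graft_D19 had more collagen RNA than Ctrl, as did Sham_D40. Over Ctrl, 17 of 19 collagens and 52 of 80 matrix genes were higher (medians 1.72 and 0.74), but Sham_D40 over Ctrl gave a matrix median of 0.88, and Graft_D19 over Sham_D40 one of 0.01. Chondrocyte markers had a median of 1.87 over Ctrl in the same cells, and the higher collagens include Col2a1, Col11a1, Col11a2 and Col1a1. Genes that exceeded both ungrafted libraries were Piezo2 (77.99 CPM against 4.29 in Ctrl), Nid2 (83.7 against 12.04), Ramp3, Col18a1 (95.4 against 14.2) and the linker histone gene Hist1h1e. Those below both were Timp4 (14.8 against 145 CPM), Tcf15 (19.5 against 109), C1qtnf9, Depp1 and Crip1. Tcf15 and C1qtnf9 are leading genes of cluster 10. Piezo2 and Ramp3 are leading genes of cluster 12, so their difference is not separate from the share of that cluster. It was 49.4% of sinusoidal-like cells in Graft_D19, 7.83% in Ctrl and 16.3% in Sham_D40. Sinusoidal identity had a median of -0.33 (7 of 18 lower) and the interferon list one of 0.36 (11 of 35 higher), but in arterial-like cells the interferon median was -0.45, with 0 of 35 higher and 8 lower. Over all measured genes of endothelium the median over Ctrl was 0.18. Stab2 was at 906 against 1213 CPM, Vcam1 at 417 against 494, Ly6a at 721 against 954, Kdr at 1458 against 1221, Pecam1 at 781 against 466 and Col4a1 at 1367 against 369.5 CPM.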

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

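The tests of free RNA, of clusters drawn by matrix genes, of pericytes and of mouse haematopoietic cells were chosen after the result was seen, and the median-cell test and the mitochondrial test of human cells after the pattern but before the tested value was seen.

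The endothelial activation list drew attention because its medians had opposite signs, -0.14 in Graft_D19 over Ctrl and 0.069 in Graft_D40 over Sham_D40; the difference between the 2 was not tested. Outside the comparisons, antibody feature B0301 held 2944081 UMIs in Sham_D40 and B0302 held 6619225 in Graft_D40. Cluster 16, led by ribosomal pseudogenes and used in no comparison, held 66 cells in Graft_D19 and 231 in Graft_D40, against 15 in Ctrl and 0 in Sham_D40.

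Matrix genes not set apart as cartilage genes were higher in LepR-marker cells of Graft_D40 than of Sham_D40. A gene was set apart when it was a chondrocyte marker or far higher in chondrocyte-like than in LepR-marker cells. Free RNA of other cells reaches endothelium too, yet for 34 of the 46 higher genes the rise was over 3 times that in endothelium. For 9 it was at most 2 times. The 46 still include genes abundant in chondrocyte-like cells of Graft_D40, such as Mgp (70567 CPM), which passed, and Sparc (38872 CPM), which did not. A minority of other cells would leave the median cell unmoved, but the median cell held 5.50% of its UMIs in 91 matrix genes against 4.17% in Sham_D40, a ratio of 1.32 (interval 1.28 to 1.35). Cluster 4 made up 79.1% of this pool in Graft_D40 and 1.59% in Sham_D40, so the median cell largely follows that share. The median cell therefore cannot exclude other cells that fill cluster 4. Clustering without the matrix genes still gave a graft-filled cluster, so the listed genes alone did not draw it. Its matrix median over the other LepR-marker cells of Graft_D40 was 0.48. That cluster was picked by its overlap with cluster 4, and leading genes outside the lists, such as Heyl and Ccn5, were not left out. The excess was also 0.40 in Ctrl and 0.25 in Sham_D40. It therefore cannot settle whether clusters drawn by matrix genes explain the difference from Sham_D40. A graft-linked stromal state stays a candidate explanation, but so do any difference between the 2 single libraries and another cell type that fills cluster 4, which is most of this pool and failed its LepR check; for cartilage genes free RNA may suffice, since 2 of 6 passed the same test and 4 rose at most 2 times as much as in endothelium.

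Acta2 and Tagln were higher in mesenchymal stroma of Graft_D40 than of Sham_D40. Pericytes or smooth muscle cells among these clusters would need a share of 1.32% of their level, whereas 4 other markers (Rgs5, Myh11, Mcam and Higd1b) gained a median of -0.019% (interval -0.0306 to -0.0076). The gain was 0.694% for Mcam, but 0.0057% for Myh11 and -0.0436% for Rgs5, which are far more abundant in pericytes. Free RNA is argued against by an Acta2 rise of 98.2 CPM against 7.16 CPM in endothelium, a ratio of 13.7. Activation of stromal cells in the grafted femur is a candidate explanation and was not tested itself.

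Cluster 16 may hold human lymphoma cells read against the mouse genome, since its cells in the grafted libraries had a median mitochondrial share of 0.1% against 2.66% in other cells, a ratio of 0.0376. Mouse haematopoietic cells are argued against by a ratio of 0.0769 to the 1.30% of haematopoietic cluster 21, and 3 of 12 haematopoietic markers were present in 25% of its cells. The 15 cells of Ctrl, at 0.481%, stay unexplained, and beyond these 2 sources of cells no biological explanation was tested.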

How the results depend on the processing

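The pool of every cluster with LepR markers, the removal of chondrocyte-like clusters and the clustering without matrix and fibroblast genes were chosen after the result was seen; the other settings were not. Of 242 values for 10 list medians and 12 shares, 108 lay inside the counting interval of the original, 133 lay outside it and 1 changed sign where the original interval lay off 0, and the cause was not tested. For endothelial matrix at day 40 the resampled interval, 0.31 to 0.46, lies above its own median of 0.30, so values close to that median also count as outside. No paired analysis was possible because each group holds 1 library. Niche factors at day 40 stayed below 0 in all 16 settings, from -1.46 to -0.86. At day 19 they ranged from -0.73 to -0.048, the last without chondrocyte-like clusters, so the day 19 difference depends on those cells. The activated-fibroblast medians of mesenchymal stroma, whose original intervals include 0, kept their sign in 9 of 16 settings at day 40 and 14 of 16 at day 19, and have no settled direction.

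Medians below are log2 and the original values are 0.16 and 0.75 for matrix in mesenchymal stroma at day 40 and day 19, 0.09 and 0.70 for matrix in LepR-like stroma, 0.06 and 0.13 for activated-fibroblast genes, -1.34 and -0.64 for niche factors, and 0.30 and 0.74 for matrix in endothelium. With Ctrl as comparator at day 40 and Sham_D40 at day 19, mesenchymal matrix was 0.93 and -0.026, the latter a reversal, LepR-like matrix 0.66 and 0.055, activated-fibroblast 0.62 and -0.23, day 40 niche -1.18, and endothelial matrix 1.29 and 0.011. Col3a1 in mesenchymal stroma at day 19 also reversed, to -0.67, and was the only reversal among 195 gene values under 4 settings, where 415 lay inside the original interval and 364 outside.

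Without mitochondrial, ribosomal and haemoglobin genes in the total, mesenchymal matrix was 0.23 at day 40, niche -1.27 and endothelial matrix at day 19 0.70. Median-of-ratios factors shifted the all-gene median of endothelium at day 19 by -0.12 and gave mesenchymal matrix 0.23, activated-fibroblast 0.13 and niche -1.26 at day 40, and endothelial matrix 0.29 and 0.62. A pseudocount of 5 gave LepR-like matrix 0.60 at day 19 and endothelial matrix 0.27 and 0.64. No minimum gave LepR-like matrix 0.60 at day 19, niche -1.27 and -0.58, and endothelial matrix 0.23 and 0.56. A minimum of 50 CPM gave mesenchymal matrix 0.23 and 0.83, activated-fibroblast -0.10 and -0.26, niche -1.44 at day 40 and endothelial matrix 0.60 at day 40. Equal weight per cell gave mesenchymal matrix 0.26 at day 40, activated-fibroblast 0.20 and 0.26, niche -0.90 and -0.15, and endothelial matrix 0.72 at day 19. Thinned cells gave mesenchymal matrix 0.25 and 0.84, activated-fibroblast 0.24 at day 40, niche -0.90 and -0.20, and endothelial matrix 0.99 at day 19. Every cluster with LepR markers gave matrix 0.67 and 0.78 in LepR-like stroma. Without chondrocyte-like clusters mesenchymal matrix was 0.42 and 0.86, activated-fibroblast 0.28 and 0.54, and niche -0.86 and -0.048.

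The stricter filter gave mesenchymal matrix 0.11 and activated-fibroblast -0.20 at day 40, and endothelial matrix 0.58 and 1.06. The looser filter gave LepR-like matrix 0.17 and 0.59 and endothelial matrix 0.67 and 0.72. Doublets kept gave mesenchymal matrix 0.08 and 0.69, activated-fibroblast -0.30 at day 40 and niche -0.59 at day 19. Resolution 0.5 gave mesenchymal matrix 0.061 and 0.64, LepR-like matrix 0.61 at day 19, activated-fibroblast -0.30 at day 40 and endothelial matrix 0.56 and 0.90. Resolution 2.0 gave mesenchymal matrix 0.12, LepR-like matrix 0.33, activated-fibroblast -0.20, niche -1.43 and endothelial matrix 0.52, all at day 40. Clustering without matrix and fibroblast genes gave mesenchymal matrix 0.057 and 0.63, and at day 40 LepR-like matrix 0.16, activated-fibroblast -0.30 and endothelial matrix 0.64. Classes from each cell's highest marker list gave mesenchymal matrix 0.062 and 0.67, LepR-like matrix 0.42 and 0.75, activated-fibroblast -0.28 at day 40, niche -1.46 and -0.73, and endothelial matrix 0.73 and 1.03; the next list scored within 0.1 for 7.43% of cells.

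Shares in percent follow the order Ctrl, Sham_D40, Graft_D19 and Graft_D40 unless a library is named. Osteolineage-like shares were 9.95, 8.04 and 13.6 in the first 3 under the stricter filter, 12.5, 17.0 and 15.1 in the last 3 under the looser one, 13.4 in Sham_D40 and 17.2 in Graft_D19 at resolution 0.5, and 4.83, 4.86, 8.88 and 7.72 at resolution 2.0. Marker-list classes gave 9.77 in Ctrl, 14.0 in Graft_D19 and 14.5 in Graft_D40. Chondrocyte-like shares were 3.74, 11.01, 16.7 and 23.8 under the stricter filter, 13.7, 11.6 and 22.4 in the first 3 under the looser one, 12.01, 11.7, 19.2 and 29.6 with doublets kept, and 13.5, 14.7, 25.6 and 37.1 by marker list. In Ctrl and Graft_D40 they were 12.01 and 30.003 at resolution 0.5, and 11.9 and 30.1 without matrix and fibroblast genes. Sinusoidal-like shares were 89.4 in Ctrl under the stricter filter, 74.4, 63.3, 57.2 and 17.7 under the looser one, 63.0, 68.9 and 33.7 in the last 3 at resolution 2.0, and 66.1, 56.3, 38.2 and 9.45 by marker list.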

Other observations

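The tests in this part were all chosen after the result was seen, and none was planned. Within Graft_D40 the graft-filled cluster found without matrix and fibroblast genes had lower niche genes than the other LepR-marker cells (median log2 -0.35, 4 of 20 lower and 0 higher), higher TGF-beta response genes (0.42, 10 of 24 higher) and lower interferon genes (-0.43, 14 of 34 lower). Interferon genes of Graft_D40 were thus higher in LepR-marker cells outside that cluster than in it. The same cluster exceeded its neighbours in matrix genes in every library, at 0.48 in Graft_D40, 0.29 in Graft_D19, 0.25 in Sham_D40 and 0.40 in Ctrl, and held 68 cells in Sham_D40 and 37 in Ctrl.

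Cluster 1 made up 63.9% of LepR-marker cells in Ctrl, 0.914% in Sham_D40, 1.99% in Graft_D19 and 0.323% in Graft_D40, so it mostly is the Ctrl library. Ctrl was also the shallowest library, and Sham_D40 over Ctrl gave matrix medians of 0.72 in mesenchymal stroma and 0.88 in endothelium. Differences of Graft_D19 from Ctrl that Sham_D40 shares cannot be assigned to the graft. Erythroid markers were lower in mesenchymal stroma, with medians of -2.02 in Sham_D40 and -3.52 in Graft_D19, both over Ctrl.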
